A study of Streptococcus thermophilus with 2 samples.

How the data were processed

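RNA was measured in 2 strains of Streptococcus thermophilus, CHCC5376 and CHCC5086, with 1 library per strain. Per the labels' protocols, precultures were grown at 37 °C in M17 broth with 2% lactose for 16 to 18 hours. They were then transferred at 1%, to an optical density at 600 nm of 0.03, into boiled skimmed milk (9.5% powder) with 0.05% tryptone. Cells were collected when the milk had reached pH 5.7. From 10 µg of total RNA per strain, ribosomal RNA was depleted with a Ribo-Zero kit, and 90-bp paired-end reads were taken on an Illumina HiSeq2000.

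A single deposited table lists 1889 features of a reference chromosome with their coordinates, which are given here as the table has them. The strain that this chromosome belongs to is not named in the table. Per the file headers, the authors gave for each library the count of total reads per feature and the count of unique reads, assigned to that feature only. The authors also gave RPKM values (reads scaled to feature length and to the sum of assigned reads). RPKM recomputed from the deposited counts and feature lengths was equal for 1889 of 1889 features within a relative tolerance of 1e-09, which tied each count column to its strain. A further deposited column holds the authors' signed fold, a score that is positive where CHCC5376 is higher and negative where CHCC5086 is higher. It holds no number for 45 features. The aligner, its settings and the treatment of strand are not given in the sources used here. Of the features, 832 carry a gene symbol and 1057 only a locus tag, which the table does not pair with a name. At most 4 of those tags are printed.

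The total reads were used as counts. Summed over features they came to 3969567 in CHCC5086 and 4103121 in CHCC5376, of which 98.0% and 98.8% were unique. A total of 44 features share reads with another and 23 have reads but no unique ones. These are named as uncertain where they appear. A further source of uncertainty is that 311 features overlap the next one, and without a stated use of strand the reads of overlapping or antisense features cannot be told apart.

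Counts were scaled with edgeR 4.0.16 (TMM, R 4.3.3), with factors of 0.932 for CHCC5086 and 1.07 for CHCC5376. For each feature a log2 ratio of CHCC5086 over CHCC5376 was computed with a prior of 0.5 counts. Folds are ratios of scaled counts, given with a 95% exact (Clopper-Pearson, conditional binomial) interval. With 1 library per strain there is no replicate check, so no p-value is given. Intervals and floors address counting error only, and they treat each read as independent. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. Both intervals and floors compare these libraries, not the strains in general. Features with at least 10 counts in 1 library or more (1618) were compared, and a difference was counted from 2-fold upward. A count of 0 was set against a floor of 3 counts per library, 7.56e-05% of the reads in CHCC5086 and 7.31e-05% in CHCC5376. Shares of reads have 95% Wilson intervals. Unless another number is given, intervals of Pearson's r and of the median absolute log2 ratio come from 2000 bootstrap draws of features. Those of Spearman's rho between the libraries and of list medians come from fewer draws.

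Before the data were examined, 23 gene lists were fixed as patterns of gene symbols. A list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. These draw scattered genes, while many list members are neighbours whose ratios go together. Each list was therefore also set, in a comparison chosen after the data were seen, among 1617 circular shifts of its positions along the chromosome, which keep the spacing of its members but do not match expression. Lists with fewer than 3 measured members received no percentile. Symbols of another function caught by a pattern were removed by name (argS, hisS, gltX, trpS, cysS, metS, ispA, rrf and deoD). The pattern for CRISPR and restriction-modification genes matched 0 features because it did not allow for numbered symbols, so those genes were gathered after their values were seen. The genes named follow a rule set at the same time as the lists. Among features with at least 50 counts in a library, these were the 12 with the largest ratio in each direction. Added to them, among the same features, were the 5 highest by RPKM per library and up to 4 members per list with the largest absolute log2 ratio, and also up to 5 features per direction at 0 in one library with at least 20 counts in the other. Any other gene named was chosen after its values were seen.

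The ratio, its interval and the 2-fold rule were tested on counts simulated for 1605 genes of this comparison. Both simulated libraries were drawn with counting error only (Poisson) around shared means, apart from the set folds. Nothing was added for variation between cultures or libraries, so coverage near 95% follows from this setting. The shares at 2-fold below are no error rates for single cultures. For 67 genes simulated at 2-fold the median log2 ratio was 1.00, 46.3% reached the 2-fold limit, and 94.0% of intervals held the true value. At 4-fold (67 genes) the median was 1.99 with 98.5% of intervals holding, and at 8-fold (66 genes) it was 3.00 with 92.4%. Of 1405 unchanged genes, 0.569% reached 2-fold and 95.2% of intervals held. Alternatives tried were scaling to total counts, DESeq2 1.42.0 size factors, a prior of 5 counts, unique reads, the deposited RPKM with a pseudocount of 1, filters of 1 and 100 counts, and a 3-fold limit. Others left out mobile element genes with the stable RNA list, or the 10 most abundant genes of each library by reads. Ribosomal protein genes were kept when the stable RNA list was left out. Alternatives added after seeing the data were leaving out features under 300 bp and keeping the pattern matches as they were. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.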

Results

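The transcriptomes of 2 strains of the dairy bacterium Streptococcus thermophilus, CHCC5376 and CHCC5086, were compared during growth in milk. Each strain was represented by 1 library, taken at pH 5.7, so no difference below has a replicate check. The library of CHCC5086 held 3969567 reads assigned to features and that of CHCC5376 held 4103121. Of the 1889 features, 145 had no reads in both libraries, 20 more were at 0 in CHCC5086 and 25 more in CHCC5376. The series sets sequencing beside microarrays, and the sequencing part is described here.

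The most abundant messages were shared by the strains. The gene for ribosomal protein L31, rpmE, led both libraries with 67366 RPKM in CHCC5086 and 82562 RPKM in CHCC5376. Elongation factor Tu, tufA, had 36562 and 38007 RPKM, and ribosomal protein L7/L12, rplL, had 9867 and 10107 RPKM. The glycolytic glyceraldehyde-3-phosphate dehydrogenase gene gapA1 stood at 40609 RPKM in CHCC5086 and 28069 in CHCC5376, a 1.66-fold difference (95% interval 1.65 to 1.68). Lactate dehydrogenase, ldh, was also among the 5 highest in CHCC5086 with 9455 RPKM and was 1.44-fold higher there (1.42 to 1.46). In CHCC5376 this place was taken by rplR, for ribosomal protein L18, with 9934 RPKM. Ranked by reads and not by RPKM, the 10 highest genes took 18.0% of the reads in CHCC5086 (Wilson 95% interval 17.9 to 18.0) and 16.7% in CHCC5376 (16.6 to 16.7).

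Most genes differed little. Of 1618 features compared, 1342 (82.9%) lay within 2-fold, 150 were at least 2-fold higher in CHCC5086 and 126 at least 2-fold lower. The whole counting interval lay beyond 2-fold for 101 of the higher and 72 of the lower features. Scaling to total counts shifted the log2 ratios by −0.20 and gave 115 higher and 177 lower, so that 39.4% of the differing features were higher in CHCC5086 in place of 54.3%. Positive log2 ratios below 0.20 can therefore change sign with this scaling, while negative ones grow in size. In the authors' deposited table, where folds come from RPKM, 115 of the compared features were at least 2-fold higher in CHCC5086 and 175 in CHCC5376. Across genes, which are not independent replicates, log2 values of the libraries correlated with Pearson's r of 0.931 (0.916 to 0.945) and Spearman's rho of 0.940 (0.926 to 0.95). The median absolute log2 ratio was 0.37 (0.35 to 0.40).

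**Figure D1:**
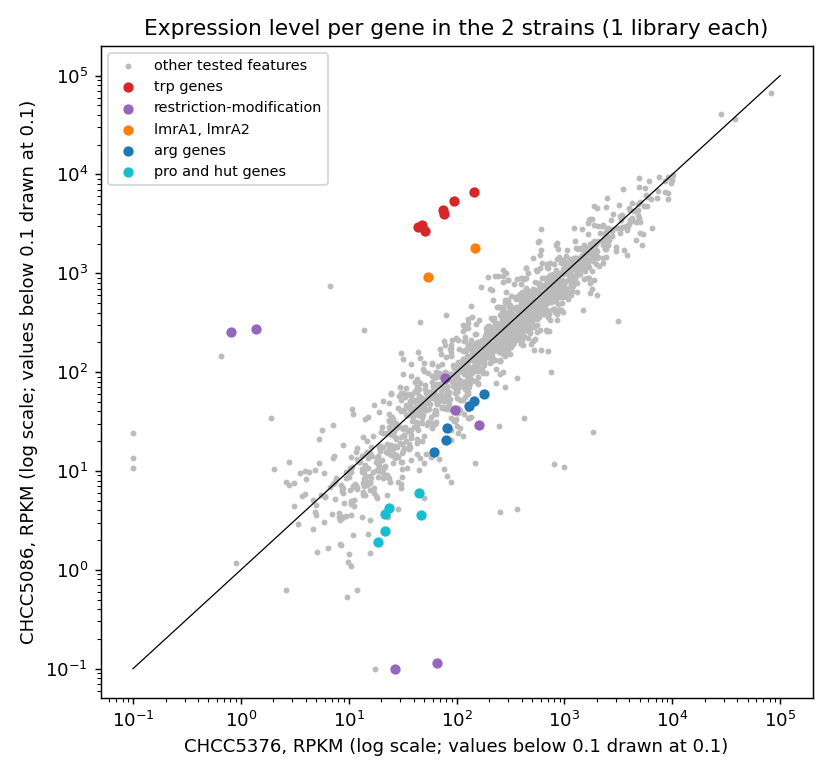
Deposited RPKM of each compared feature in CHCC5376 (horizontal, log scale) and CHCC5086 (vertical, log scale), 1 point per feature, with values below 0.1 drawn at 0.1 and the line marking equal values. The 7 trp genes lie at 2703 to 6568 RPKM in CHCC5086 against 43.8 to 146 RPKM in CHCC5376, far above the line.

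Tryptophan synthesis genes were 7 of the 12 features with the largest differences toward CHCC5086. All 7 trp genes, which encode the enzymes from chorismate to tryptophan and lie side by side at positions 1405000 to 1411351, were 51.6-fold to 77.5-fold higher in CHCC5086. The extremes were trpA (51.6-fold, 95% interval 47.1 to 56.7) and trpG (77.5-fold, 63.7 to 95.2). Between them, trpE was 74.4-fold, trpC 67.2-fold, trpB 65.2-fold, trpD 60.8-fold and trpF 59.7-fold higher. Together the genes took 103413 reads (2.61%) in CHCC5086 and 1950 reads (0.0475%) in CHCC5376. The neighbouring feature stu1594, at 1411413 to 1411703, was 127-fold higher (64.3 to 296).

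Several restriction-modification genes, which cut or methylate DNA at set sequences, had reads almost only in one library, and hsdR1 and sthII had the largest ratio in each direction among features with at least 50 counts in a library and reads in both. The type I restriction subunit gene hsdR1 (661355 to 664345) had 3003 reads in CHCC5086 and 10 in CHCC5376, a 357-fold difference (194 to 745). Its methylase partner hsdM1 (670817 to 672421) had 1743 and 9 reads, or 230-fold (121 to 504). Between them, the feature stu0710 had 434 and 2 reads, or 258-fold (71.0 to 2137). The other 4 features between them, at 664335 to 669987, had 0 reads in both libraries. In the opposite direction, sthII (1205092 to 1209504) had 2 reads in CHCC5086 and 1193 in CHCC5376, 502-fold lower in CHCC5086 (139 to 4147). The adjacent llaBIIM (1209511 to 1210185) had 0 reads in CHCC5086 and 75 in CHCC5376, which makes it at least 21.0-fold lower against the floor of 3 counts (the exact 95% interval starts at 16.7-fold). Chosen after their values were seen, sthIR was 4.83-fold and sthIM 2.05-fold lower in CHCC5086, hsdS2 was 1.29-fold higher, and hsdS1 had no reads in both libraries. Apart from llaBIIM, 1 feature was at 0 in one library with at least 20 reads in the other, an unnamed 282-bp feature with 27 reads in CHCC5086, at least 10.7-fold higher there against the same floor (the exact 95% interval starts at 8.12-fold).

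The other features with the largest differences toward CHCC5376 were mostly without a gene name. A run of 5 unnamed neighbours at 291302 to 294646 was 56.7-fold to 79.8-fold lower in CHCC5086, with 123 reads there and 10054 in CHCC5376. It includes stu0297 (79.8-fold, 58.2 to 112) and stu0299 (76.8-fold, 35.1 to 210). The transporter gene proWY was 11.3-fold lower (6.45 to 21.7) and the signal peptidase gene sipB 10.7-fold lower (8.49 to 13.7). Over all compared features, 18 were at least 10-fold higher in CHCC5086 and 13 at least 10-fold lower.

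**Figure D2:**
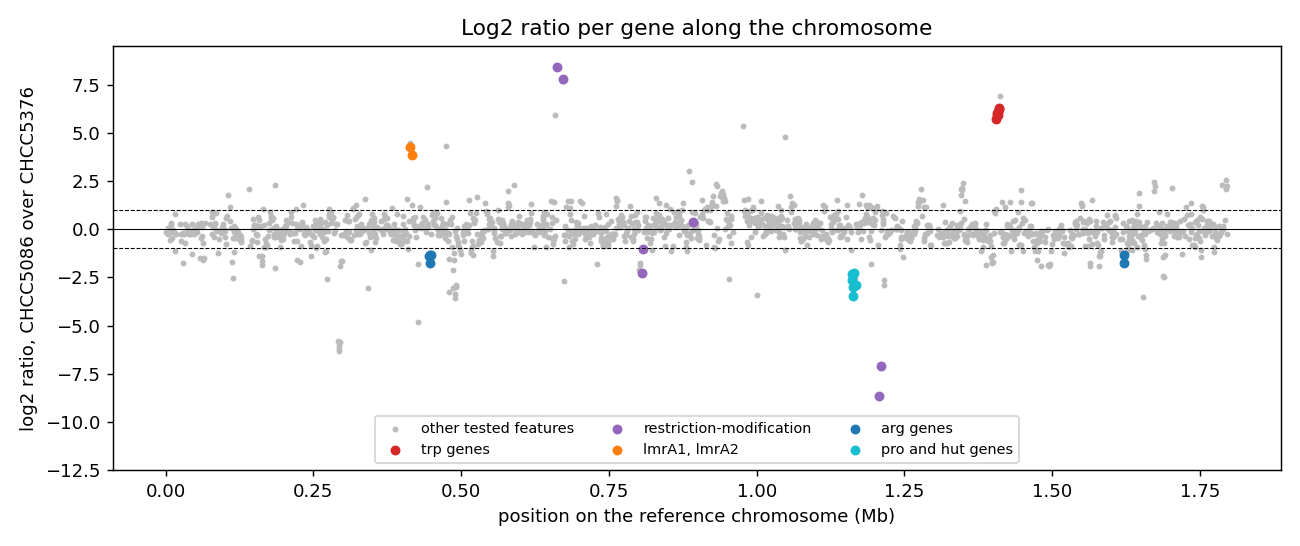
Log2 ratio of CHCC5086 over CHCC5376 for each compared feature (vertical) by its position on the reference chromosome in Mb (horizontal), with dashed lines at 2-fold. A feature at 0 in one library is drawn at its ratio with a prior of 0.5 counts, which is no bound, and the trp genes form a cluster near a log2 ratio of 6.02.

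Of 21 measured genes of proteolysis and peptide transport, 11 were at least 2-fold higher in CHCC5086, 0 were that much lower and 10 lay within 2-fold, with a median log2 ratio of 1.06 that lay at percentile 100 among matched random lists. The quality-control protease gene htrA was 4.69-fold higher (4.41 to 4.98) and codY, which encodes a regulator of amino acid metabolism, 4.10-fold higher (3.81 to 4.41). The oligopeptide transporter gene amiD was 2.96-fold higher (2.82 to 3.11). Named after their values were seen, the transport genes amiA3, amiC, amiE, amiF1 (some reads shared) and dtpT were also among the higher members. So were the peptidase genes pepC and pepV. The 10 members within 2-fold were the remaining peptidase genes and prtM (ratio 1.03). Of these, pepA and pepM were 1.25-fold (1.16 to 1.35) and 1.16-fold lower. With scaling to total counts 9 members were at least 2-fold higher. The gene amiA2 was 4.25-fold higher, but none of its reads were unique to it. With unique reads the list had 20 members and a median of 0.85.

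Of 14 measured branched-chain amino acid genes, 7 were at least 2-fold higher in CHCC5086 and 0 that much lower (median log2 ratio 1.00, percentile 100). The reductoisomerase gene ilvC was 5.37-fold higher (5.14 to 5.61). The acetolactate synthase genes ilvB and ilvN were 4.78-fold (4.52 to 5.05) and 3.95-fold higher (3.44 to 4.55), and leuB was 2.56-fold higher (2.30 to 2.86). All 7 were synthesis genes. Named after their values were seen, the uptake gene livJ was 1.71-fold higher (1.59 to 1.84), livF, livH and livM were 1.30-fold to 1.37-fold higher and livG had a ratio of 0.972.

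The remaining amino acid synthesis genes went both ways. Of 39 measured, 10 were at least 2-fold higher and 6 lower, and the list median of 0.12 lay at percentile 81.4 and became −0.08 with scaling to total counts. The higher members were the 7 trp genes, serA and serC of serine synthesis, at 4.42-fold and 5.33-fold, and asd. A further serine synthesis gene, serB, named after its values were seen, was 1.28-fold lower (1.13 to 1.45). The 6 lower members were the arginine synthesis genes argB, argC, argD, argG, argH and argJ, 2.5-fold to 3.39-fold lower in CHCC5086. Named after their values were seen, argF and argR had ratios of 1.12 (0.751 to 1.68) and 1.20 (0.873 to 1.66). Sulphur amino acid genes had 0 of 12 members at 2-fold, with a median of −0.13, a mean of opposite sign (0.0031) and a percentile of 20.1. Their largest ratios were metE at 1.79-fold, hom at 1.65-fold and metF at 1.56-fold higher, and cysM1 at 1.58-fold lower.

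The lactose and galactose list, which covers the sugar of milk, had 0 of 9 members at 2-fold, and its median log2 ratio of 0.08 (percentile 58.1) became −0.12 with scaling to total counts. Within it the beta-galactosidase gene lacZ was 1.60-fold (1.58 to 1.62), the lactose transporter gene lacS 1.49-fold and galE2 1.46-fold higher. The ratio of galT, 1.13-fold, falls within the shift between scalings. Of 17 glycolysis genes, 3 were at least 2-fold higher and 0 lower (median 0.47, percentile 98.2). These were the mutase gene gpmA at 2.36-fold (2.31 to 2.42), gapN, for a non-phosphorylating glyceraldehyde-3-phosphate dehydrogenase, at 2.36-fold, and ptsH, for the phosphocarrier protein HPr, at 2.24-fold. The gene ptsI was 1.90-fold higher, while gpmC, named after its values were seen, was 1.47-fold lower (1.32 to 1.64). Without features under 300 bp the glycolysis percentile was 94.8, and without the 10 most abundant genes 96.8, both inside the central 95%. Of 11 genes for other sugars, 4 were at least 2-fold higher (median 0.55, percentile 99.4, and 96.8 among shifted positions, inside the central 95%), namely scrB (2.55-fold), manN (2.37-fold), malQ (2.06-fold) and glgP (2.03-fold). With scaling to total counts 2 of them passed 2-fold and 1 other member was 2-fold lower.

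**Figure D3:**
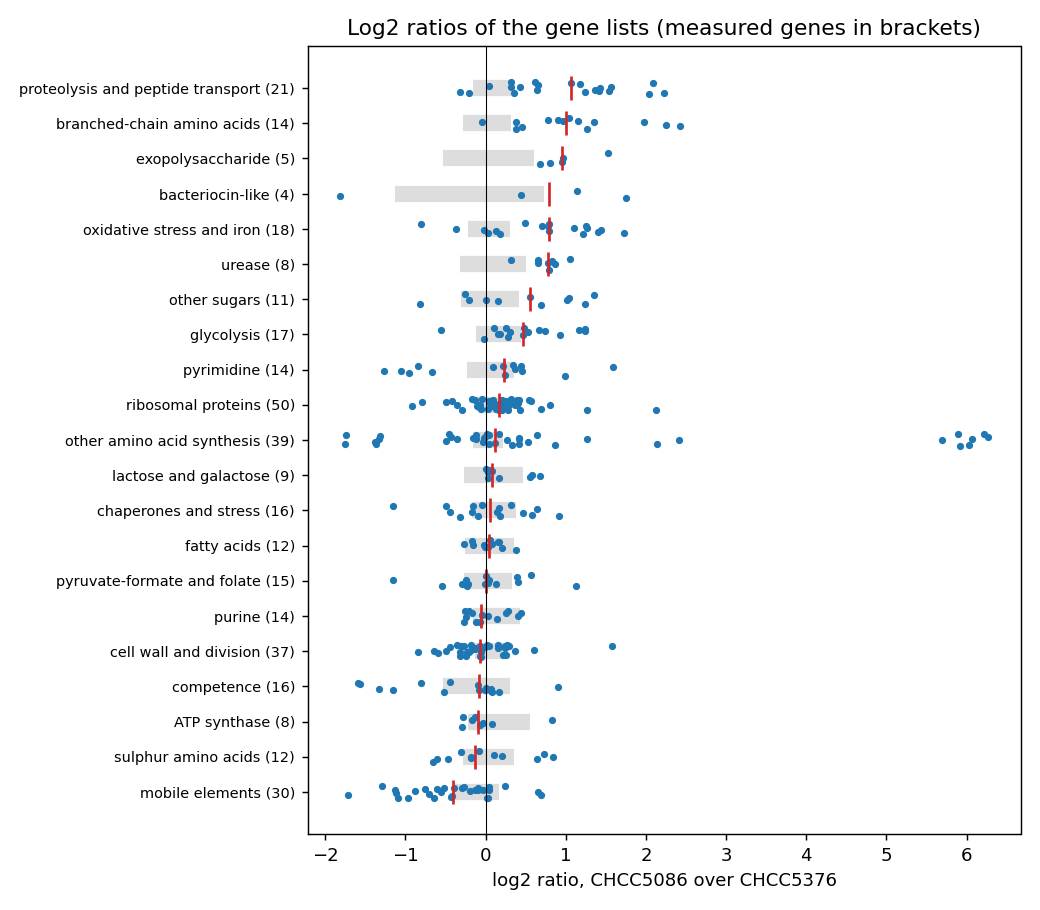
Log2 ratio of CHCC5086 over CHCC5376 (horizontal) for the measured members of each list with at least 3 of them (rows), 1 point per gene, with the list median as a red mark and the central 95% of medians of 10000 matched random lists as a grey bar. Of 21 lists, 8 medians lie above the bar and 1 below it, although the bar takes no account of neighbouring genes that differ together.

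Of 18 measured genes for iron handling and oxidative stress, 7 were at least 2-fold higher in CHCC5086 and 0 that much lower (median 0.79, percentile 99.99), or 6 higher and 1 lower with scaling to total counts. That 1 was msrA2, 1.75-fold lower with the main scaling (1.35 to 2.28). The thioredoxin reductase gene trxB2 was 1.29-fold lower (1.20 to 1.38), and the ferrous iron genes feoA and feoB had ratios of 1.02 and 0.990. These 4 were named after their values were seen. Among the higher members were the iron transport genes fatD (3.31-fold, 3.16 to 3.47) and fatC (2.64-fold, 2.48 to 2.80). The superoxide dismutase gene sodA was 2.70-fold (2.63 to 2.78) and the methionine sulfoxide reductase gene msrA1 2.40-fold higher (2.13 to 2.70). Urease genes had a median of 0.78 (percentile 99.7) over 8 members, of which 1, ureI, reached 2-fold (2.07-fold) and 0 did so with scaling to total counts. Among shifted positions, which keep the list's neighbours together, its percentile was 95.1, inside the central 95%. The genes ureG, ureC and ureB were 1.83-fold, 1.77-fold and 1.73-fold higher.

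Of 17 exopolysaccharide genes, 5 could be measured, with a median of 0.95 (percentile 99.5, and 94.7 among shifted positions, inside the central 95%). One of them was at least 2-fold higher, epsE (2.92-fold, 1.75 to 5.03, from 54 and 22 reads). With a filter of 100 counts 4 members were left and 0 reached 2-fold. The genes epsC, epsD and epsA were 1.96-fold, 1.93-fold and 1.74-fold higher. A stretch of 15 features from 960557 to 974935, of which 10 are named, had 0 reads in both libraries.

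Several lists held genes lower in CHCC5086. Among 16 genes matched by the pattern for competence (DNA uptake), not all of which need act in uptake, 4 were at least 2-fold lower and 0 higher. The median was nevertheless −0.09 (percentile 51.7). The 4 lower genes were cinA (3.01-fold, 2.86 to 3.15), comGA (2.98-fold, 2.16 to 4.16), comGB (2.52-fold, 1.86 to 3.47) and comEC (2.24-fold, 1.46 to 3.54, from 30 and 80 reads). With a filter of 100 counts 8 competence members were left, with 3 at least 2-fold lower, a median of −0.27 and a percentile of 15.6. Among 14 pyrimidine genes the carbamoyl phosphate synthase genes carB and carA were 2.41-fold and 2.09-fold lower, while pyrC was 3.02-fold and pyrE 1.99-fold higher. That list had a median of 0.23 (percentile 90.1) and a mean of opposite sign (−0.0038), and with scaling to total counts 4 members were 2-fold lower. Mobile element genes had a median of −0.41 over 30 members (percentile 1.94), with 5 at least 2-fold lower and 0 higher. The percentile was 31.9 with unique reads, which left 11 members, and 33.8 with a filter of 100 counts. Of the members with at least 50 counts in a library, an int gene was 2.17-fold lower. A copy of tnp1191, most of whose reads were shared with other features, was 2.47-fold lower, and tnpSth1 copies at 821983 and 742068 were 2.15-fold and 1.85-fold lower with no unique reads.

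In the chaperone and stress list, 1 of 16 genes reached 2-fold, clpL (2.23-fold lower, 2.16 to 2.30), while groES was 1.88-fold, groEL 1.56-fold and cspB 1.5-fold higher. Its median of 0.05 (percentile 48.8) became −0.15 with scaling to total counts and −0.03 without features under 300 bp. In the pyruvate, formate and folate list, the pyruvate formate-lyase gene pfl was 2.22-fold lower and folD 2.19-fold higher among 15 genes, with adhB 1.49-fold higher and folC1 1.46-fold lower. Its median was 0.00 (percentile 51.1) and −0.20 with scaling to total counts. The bacteriocin-like list had only 4 measured genes, of which blpA was 3.54-fold lower, labB 3.41-fold and labC 2.22-fold higher and labT 1.36-fold higher. Its median was 0.79 (percentile 98.1) and −0.69 over the 2 genes with at least 100 counts. Its percentile was inside the central 95% with unique reads (96.6), without mobile element and stable RNA genes (97.2) and among shifted positions (94.1).

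Of 50 ribosomal protein genes, 2 were at least 2-fold higher, rpsU (2.42-fold) and rpmD (4.61-fold, 2.07 to 11.6, from 31 and 8 reads), and rpmB was 1.75-fold higher. Without features under 300 bp 0 of 34 members reached 2-fold, and with a filter of 100 counts 1 of 46 did. The genes rpsO and rplM were 1.89-fold and 1.73-fold lower. The list median of 0.17 (percentile 89.1) became −0.04 with scaling to total counts. No member reached 2-fold among 14 purine genes (median −0.06, percentile 14.9, mean of opposite sign at 0.013), 8 ATP synthase genes (median −0.10, percentile 14.5) and 12 fatty acid genes (median 0.04, percentile 57.0, and −0.16 with scaling to total counts). Their largest ratios were purR at 1.36-fold, atpE at 1.77-fold and acpS at 1.30-fold higher. The atpE feature is only 198 bp long, and without features under 300 bp the ATP synthase list had 7 members and a median of −0.12. Among 37 cell wall genes murO was 2.99-fold higher and murC 1.80-fold lower, with a median of −0.07 (percentile 10.2). The stable RNA list held only ssrA, the transfer-messenger RNA, with 228 RPKM in CHCC5086 and 292 in CHCC5376.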

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

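Leaving out features under 300 bp, keeping the pattern matches as they were and shifting list positions are the alternatives that were chosen after the data were seen. No paired analysis was possible because the labels give 1 library per strain and no shared replicate numbers, and no library could be left out. Of values recomputed for named genes, 925 stayed within their counting interval and 194 moved; of list medians, 192 stayed within their bootstrap interval, 25 moved and 1 reversed, where a change of sign counts as a reversal only for the 9 lists outside the central 95% of random lists. Medians of 6 other lists changed sign with total counts. The median absolute log2 ratio was 0.43 with total counts and 0.43 with RPKM, since both omit the TMM factors. Pearson's r and Spearman's rho were 0.911 and 0.924 with RPKM, 0.95 and 0.951 with no filter, and 0.872 and 0.908 with a filter of 100 counts, which tests fewer genes. That filter left 122 features higher and 71 lower in CHCC5086 (63.2% higher) and gave the bacteriocin-like list a median of −0.69 over its 2 remaining genes. A 3-fold limit gave 56 higher and 66 lower, with the whole interval beyond it for 42 and 27. At 0 in one library there were 5 features when up to 2 counts were allowed, among them sthII and llaBIIM, and 0 when 100 counts were required in the other. A list's mobile element or stable RNA value cannot be given once those genes are left out. The authors' column states no fold limit, so replacing it was not run. Depth limits the genes with few reads in one library, whose intervals span several-fold.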

Other observations

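The genes and groups in this part were chosen after their values were seen, and so were the tests, except those of gene dosage and of gene length against the signed ratio.

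Several groups of genes outside the fixed lists differed between the libraries. The acetoin dehydrogenase genes acoA, acoB, acoC and acoL at 936948 to 942413 were 3.13-fold to 3.91-fold higher in CHCC5086. The transporter genes lmrA1 and lmrA2 were 19.4-fold (17.6 to 21.6) and 14.2-fold (13.3 to 15.1) higher. The single genes amtB, for an ammonium transporter, and dagA were 20.8-fold (11 to 44.2) and 8.18-fold (7.16 to 9.37) higher. Lower in CHCC5086 were the transporter genes proV, proWX, proWY and proWZ with the neighbouring histidine degradation genes hutH and hutU, by 4.91-fold to 11.3-fold, although these 6 genes had only 87 reads in CHCC5086 and 717 in CHCC5376. The gene umuC1, for a DNA polymerase of the SOS response, was 7.53-fold lower (6.39 to 8.92). Within the pyrimidine list, the 5 genes from pyrR to carB, at 493836 to 501781, were 1.59-fold to 2.41-fold lower.

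The trp genes had a median log2 ratio of 6.02. Library scaling and a few abundant genes are argued against, since the lowest median over the alternatives was 5.81. Reads shared with near-identical copies are argued against too, since 100% of the reads of each gene were unique. A difference between the strains stays open as untested. It cannot be told apart from the state of a single culture, because there is 1 library per strain.

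Features without reads in both libraries included many short ones and runs of longer ones. Under 200 bp, 70.9% of 127 features were at 0 in both, against 3.12% of longer ones, including 5 of 9 ribosomal protein genes under 200 bp, so loss of short features in the library or the alignment may account for these. Of features from 200 bp to under 250 bp, 17 of 119 were at 0, and from there to under 300 bp 5 of 97. Of the 1546 features of 300 bp or more, 33 were at 0, and 19 neighbouring pairs were both at 0, while the highest of 10000 shuffled orders gave 5. Blocks of the reference that both strains lack or carry in a diverged form would give such runs. Examples of runs are the eps stretch and the 4 features at 664335 to 669987 that include hsdS1. Neighbouring genes that are present but silent together would give runs too. Shuffled orders break up neighbours that go together, so they cannot separate these cases. No genome of either strain was used here, so absence, divergence and lack of expression stay open.

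Absence or divergence in one strain may also account for the one-sided restriction-modification genes, but no value here decides it. The RPKM of hsdR1, hsdM1 and stu0710 in CHCC5376 reached at most percentile 0.799 among 1501 features of 300 bp or more with reads, and that of sthII and llaBIIM in CHCC5086 percentile 0 among 1506. These genes were chosen for their few reads, so the low percentiles restate that choice, and genes that are present and silent would give the same values. For the 5 unnamed neighbours at 291302 to 294646 the highest percentile in CHCC5086 was 15.6. This value belongs to the highest of the 5 genes, whose RPKM there ran from 3.86 to 24.5. The limit it was set against was chosen after the values were seen. It cannot separate absence of some of the genes, divergence and lower expression, which stay open as untested.

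A hypothesis of gene dosage between origin and terminus gave a median log2 ratio 0.28 higher in positions far from the first feature than in positions near it (the outer and inner of 3 equal parts), with an interval of 0.13 to 0.39 (1000 bootstrap draws of blocks of 20 features) that includes the 0.2 set as the limit in advance. Split by arm after this was seen, the difference was 0.19 on the arm after the first feature and 0.36 on the other. Neighbouring features may differ together, since Spearman's rho of their log2 ratios was 0.411 across genes against at most 0.0832 in 1000 shuffled orders. Operons would give this, but so would reads counted in overlapping features or a trend along the chromosome. Shuffled orders remove all of these, so the comparison cannot tell them apart. Gene length had a rho of −0.0058 with the signed log2 ratio (−0.054 to 0.043 from 1000 bootstrap draws of features), which says nothing of the spread. With the absolute ratio rho was −0.090 (−0.138 to −0.044), so that shorter features scattered slightly more. This lies within the limit of 0.2 and argues against length as the main source of the spread.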
